A study of Drosophila melanogaster with 9 samples.

How the data were processed

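Stranded poly(A) libraries were made from 100 ng of RNA, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 and the dm3 build, without role or order. The read counter, its strand setting, the annotation and any filters are not given in the sources used here. The authors deposited RPKM values (reads scaled by gene length and library depth) for 15682 genes in 9 libraries, of which 3246 genes were at 0 in all libraries. Symbols and positions were matched by gene identifier for 15002 genes in the BDGP6 annotation, a different build from dm3. All coordinates here are BDGP6, and none were converted between builds.

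RPKM values are not counts, so no count test gave the main result. Low values in each library were whole multiples of what 1 read is worth, which gives the depth: 30444292, 30020187 and 32520573 reads in the CR32027-IR1 libraries, 36512316, 29585548 and 25070343 in CR32027-IR2, and 25435056, 27333740 and 34333231 in OreR. A gene length making all 9 values whole within 0.01 read was found for 8452 of 8487 genes tried (99.6%). For 3841 genes with introns that were compared with BDGP6, 79.5% of these lengths lay within 2% of the genomic span and 0.338% within 2% of the exonic length. Introns thus lower a gene's RPKM for its reads, and 330 genes with at least 50 reads on average had a mean under 1 RPKM. Intervals from reads cover counting error only, since reads carry no molecular identifiers.

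Groups came from the sample labels. Values were taken as log2(RPKM + 1), and genes with a mean of at least 1 RPKM over the 9 libraries were kept (7437). limma 3.58.1 in R 4.3.3 with an intensity trend was fitted to all 9 libraries at once, with 6 residual degrees of freedom. Each hairpin genotype was compared with OreR, and CR32027-IR1 with CR32027-IR2. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. The median log2 change of all genes was 0.01 for CR32027-IR1 and -0.02 for CR32027-IR2. CR32027 was also compared by an exact permutation test.

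Before the data were examined, 44 gene lists, the tests, the alternatives and a rule for naming genes were fixed. The 40 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Past 0.05 were 6 lists for CR32027-IR1, 8 for CR32027-IR2 and 6 for the direct contrast, whose list test was added after the data were seen; with an estimated correlation 0 lists passed in each. The rule took CR32027, w, Dcr-2, Bx and tio; the 12 largest rises and 12 largest falls called in both hairpin genotypes with libraries apart from OreR; the 8 largest of each direction in either; the 5 largest of each direction between the hairpins; up to 4 members of each list with the smallest p; and 2 neighbours of CR32027 on each side. Some are summarised without a name, and genes outside the rule are marked as named after their values were seen.

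Overlap with no gene changed was simulated 100 times, with groups set against the same controls. Alternatives covered the pseudocount, filter, scaling, trend, array weights, libraries fitted, a replicate block, thresholds and leaving out each library. Added after the data were seen were limma voom on the recovered reads, protein-coding genes alone and array weights estimated gene by gene. The fit was tested on simulated data. For CR32027-IR1 against OreR (7417 genes) 76.1%, 96.9% and 98.4% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered and 0.138% of unchanged genes were called. For CR32027-IR2 against OreR (7421 genes) these were 79.1%, 92.4%, 98.5% and 0.111%. Simulated genes were independent and had the same spread in all genotypes, so these rates need not hold for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for annotation, read recovery and figures.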

Results

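Gene expression was measured in the wing pouch of Drosophila melanogaster larvae carrying hairpin RNAs against the noncoding RNA CR32027. The wing pouch is the part of the larval wing disc that forms the wing blade. Hairpins were driven by Bx-GAL4 (MS1096), a driver active in the wing pouch, together with UAS-dicer2, which supplies extra Dicer-2 for hairpin processing. Fathers came from the stocks CR32027-IR1 (VDRC 26860) and CR32027-IR2 (VDRC 103512) or from the wild-type strain OreR, and mothers from the driver stock (Bloomington 25706). From male larvae raised at 25 °C, 30 discs were dissected and the nota removed before RNA extraction. There were 3 libraries for each of the 3 genotypes. Nothing states that the 3 libraries of a genotype came from separate crosses, so p-values measure the spread between these libraries, which may be technical. The steps between low values corresponded to 25070343 to 36512316 reads per library. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.983 to 0.995 within genotypes and 0.976 to 0.988 between them.

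CR32027 (FBgn0052027) was examined first, to ask whether the hairpins lowered their target. It was lower than in OreR in CR32027-IR2 and was not lower in the libraries labelled CR32027-IR1. Its level was 2.74 ± 0.495 RPKM in OreR, 0.905 ± 0.432 in CR32027-IR2 and 3.57 ± 0.793 in the libraries labelled CR32027-IR1 (mean ± SD of 3 libraries, as throughout). CR32027-IR2 had 33.1% of the OreR level, a log2 change of -0.99 ± 0.19 (SE; limma, adjusted p = 0.0171). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Without OreR replicate 2 the log2 change was -0.885 and did not pass (limma, adjusted p = 0.0778). In the libraries labelled CR32027-IR1 the log2 change was 0.29 ± 0.19 (95% interval -0.14 to 0.71; limma, adjusted p = 0.348; exact permutation p = 0.2). The target thus gives no check of the label there, so directions given below for those libraries refer to the label alone. Between the hairpin genotypes the log2 difference was 1.28 (limma, adjusted p = 0.00214).

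**Figure D1:**
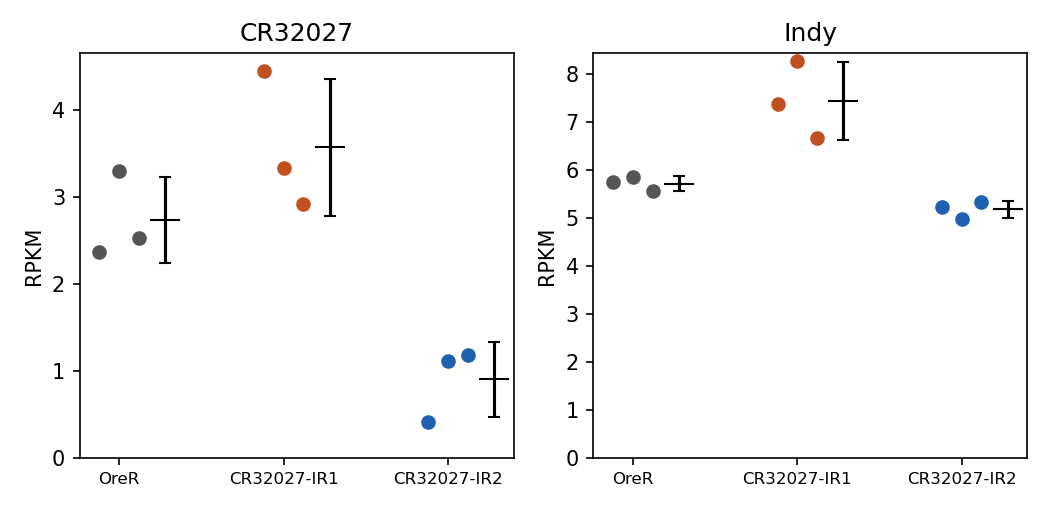
RPKM of CR32027 (left) and of Indy (right) in each library (points) with the mean ± SD of 3 libraries (bars), for OreR, CR32027-IR1 and CR32027-IR2. CR32027 averaged 2.74 in OreR, 3.57 in the libraries labelled CR32027-IR1 and 0.905 in CR32027-IR2.

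CR32027 lies on the plus strand of chromosome arm 3L from 18841579 to 18842786 (BDGP6) and has 3 exons. It sits within Indy, a citrate transporter gene on the minus strand, and shares 0 exon bases with it. The CR32027 values rest on 287 reads over the OreR libraries, 94 over the CR32027-IR2 libraries and 400 over those labelled CR32027-IR1. The lowest library value, 18 reads, has an exact 95% Poisson interval of 10.7 to 28.4. Whether the authors' counting used strand is not given in the sources used here, so it is not known whether reads of the Indy intron were kept apart from CR32027. At another locus plus-strand Mul1 had 580 reads over the OreR libraries, and minus-strand CG11594, whose BDGP6 span overlaps it, had 2. If the authors' gene models overlap there too, these values argue against unstranded counting at that locus. Strand use at CR32027 itself was not tested. Indy was 5.72 ± 0.152 RPKM in OreR, 5.18 ± 0.175 in CR32027-IR2 (limma, adjusted p = 0.446) and 7.44 ± 0.809 in the libraries labelled CR32027-IR1 (adjusted p = 0.02). That Indy call was lost without CR32027-IR1 replicate 1 (0.0614) or OreR replicate 1, 2 or 3 (0.0551, 0.0575 and 0.062). The neighbours Cat, HipHop and CG14074 did not pass in either comparison with OreR.

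RNAs related to the transgenes also differed between genotypes. Dcr-2, whose signal can include the UAS transgene, fell from 859 ± 89.8 RPKM in OreR to 470 ± 78 in the libraries labelled CR32027-IR1 (limma, adjusted p = 0.0026) and 535 ± 50.8 in CR32027-IR2 (adjusted p = 0.0141). The Dcr-2 call in CR32027-IR2 was lost without CR32027-IR2 replicate 1 or 2 (0.0575 and 0.0632) or OreR replicate 1 or 2 (0.0635 and 0.0656). The eye pigment transporter gene w, a common transgene marker, rose from 446 ± 16.5 to 568 ± 21.4 RPKM in CR32027-IR2 (adjusted p = 0.00889). It was 399 ± 23.3 in the libraries labelled CR32027-IR1 (adjusted p = 0.103), and passed there as lower without CR32027-IR1 replicate 2 (0.0334) or with array weights gene by gene (0.00762). The zinc finger gene tio fell from 7.16 ± 0.909 to 3.86 ± 0.792 RPKM in CR32027-IR2 (adjusted p = 0.0102) and was 8.21 ± 0.946 in the libraries labelled CR32027-IR1 (adjusted p = 0.404). Bx was not analysed here.

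The glycolytic enzyme genes Pfk and Eno, the proneural genes ac and sc, smo of the Hedgehog pathway and msl-2 of the dosage compensation machinery were lower in the libraries labelled CR32027-IR1 than in OreR. Phosphofructokinase (Pfk), which commits sugar to glycolysis, fell from 21 ± 0.364 to 11.4 ± 0.667 RPKM (log2 change -0.83; limma, adjusted p = 2.22e-05). Enolase (Eno) fell from 117 ± 3.28 to 70.9 ± 8.16 RPKM (-0.72; adjusted p = 0.000571). The proneural genes ac and sc, which specify sensory organ precursors, fell from 15.8 ± 0.98 to 11 ± 0.489 RPKM (adjusted p = 0.00268) and from 16.5 ± 1.11 to 10.5 ± 1.33 (adjusted p = 0.00423).

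Of 14 glycolysis genes 5 fell and 0 rose. Without CR32027-IR1 replicate 3 the 5 became 8. Adjusted over the list alone, with all libraries, 10 fell. Besides Pfk and Eno, the 5 were Pglym78 (-0.39; limma, adjusted p = 0.00174) and, named after their values were seen, Tpi (-0.47; 0.00536) and Gapdh2 (-0.36; 0.00339). Camera gave the list adjusted p = 7.56e-06, and adjusted p = 0.317 with an estimated correlation. Lactate dehydrogenase (Ldh) was 2.3 ± 0.32 RPKM in OreR and 1.32 ± 0.486 in the libraries labelled CR32027-IR1 (limma, adjusted p = 0.0507).

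In the Hedgehog list 5 of 15 genes fell: smo, the pathway's signal transducer (34.5 ± 1.19 to 27.6 ± 0.745 RPKM; limma, adjusted p = 0.00352), fu (-0.35; 0.00618), Su(fu) (-0.25; 0.00964), boi and cos. The last 2, named after their values were seen, were lost without OreR replicate 2 (0.0575 and 0.0657), and cos also without CR32027-IR1 replicate 1 (0.0624) or OreR replicate 1 (0.0565). The list had camera adjusted p = 0.0142, and adjusted p = 0.782 with an estimated correlation. It did not pass without CR32027-IR1 replicate 3 (0.0885) or OreR replicate 3 (0.0556), and with array weights Su(fu) did not pass (0.0715). In the dosage compensation list, which holds the machinery that raises X-linked expression in males, 4 of 10 genes fell: msl-2 (-0.36; limma, adjusted p = 0.00212), mof (-0.36; 0.00878) and the noncoding RNAs roX1 (-0.28; 0.00692) and roX2 (-0.55; 0.0104). In this list 5 fell when adjusted over the list alone. Camera gave this list adjusted p = 0.0142, and adjusted p = 0.782 with an estimated correlation.

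Among 11 wing pouch genes 3 fell, the transcription factor genes nub, pdm2 and dve (camera adjusted p = 0.0142; adjusted p = 0.782 with an estimated correlation). Adjusted over the list alone 4 fell. All 3 calls were lost without OreR replicate 1 (0.0726, 0.066 and 0.0916) or 2 (0.0575, 0.0929 and 0.0865). Single calls were also lost without CR32027-IR1 replicate 1 (nub, 0.0617), CR32027-IR1 replicate 3 (pdm2, 0.0572; dve, 0.0591) or OreR replicate 3 (dve, 0.0599), and the list did not pass without CR32027-IR1 replicate 3 (0.113) or with genes of at least 5 RPKM (0.0584). The Wingless secretion gene wls fell from 62.4 ± 0.946 to 44.1 ± 0.636 RPKM (limma, adjusted p = 0.000113), while the Wingless list, with wls and lgs lower of 18 genes, did not pass (camera adjusted p = 0.159). The lgs call was lost without CR32027-IR1 replicate 1 (0.0665) or OreR replicate 2 or 3 (0.0656 and 0.0706). The sensory organ list, with ac, sc and E(spl)m4-BFM lower among 10 genes, did not pass either (adjusted p = 0.111), and with array weights E(spl)m4-BFM was not called (0.0667).

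Lists past the threshold in the upward direction had few called members. The 82 ribosomal protein genes had a median log2 change of 0.15, with RpS27 called higher and RpS19b lower (camera adjusted p = 9.95e-06; adjusted p = 0.782 with an estimated correlation). RpS27 lost its call without CR32027-IR1 replicate 1 (0.0644) or OreR replicate 1, 2 or 3 (0.0529, 0.0575 and 0.0765), and RpS19b without CR32027-IR1 replicate 1 (0.0753). In the S phase list 1 of 21 genes was called, the DNA polymerase gene PolA1 (camera adjusted p = 0.0142; adjusted p = 0.782 with an estimated correlation). PolA1 lost its call without CR32027-IR1 replicate 1 or 3 (0.144 and 0.0768), CR32027-IR2 replicate 2 or 3 (0.0648 and 0.0638) or OreR replicate 1, 2 or 3 (0.136, 0.0521 and 0.102). Adjusted over the list alone, none of RpS27, RpS19b and PolA1 was called. The S phase list did not pass without CR32027-IR1 replicate 3 (0.0503) or OreR replicate 1 (0.109).

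The apoptosis inhibitor Diap1 rose from 38.2 ± 1.45 to 45 ± 0.653 RPKM (limma, adjusted p = 0.00816), the MAP kinase gene rl rose from 5.13 ± 0.339 to 7.29 ± 0.355 (adjusted p = 0.00423), and the Jun kinase gene bsk fell from 33.6 ± 1.14 to 25.4 ± 0.364 (adjusted p = 0.00174). The pro-apoptotic gene rpr went from 24 ± 4.02 to 16.2 ± 3.01 RPKM (adjusted p = 0.0317), a call lost without CR32027-IR1 replicate 1 or 2 (0.107 and 0.0569) or OreR replicate 1, 2 or 3 (0.0537, 0.0537 and 0.0837). Of 13 apoptosis genes Diap1 and the caspase gene Dcp-1 were higher and rpr lower, and the list did not pass (camera adjusted p = 0.953). The Dcp-1 call was lost without CR32027-IR1 replicate 1 (0.0544) or OreR replicate 1 or 2 (0.0514 and 0.0575), with array weights (0.0667) or with only these genotypes fitted (0.0619). The JNK and wound list, with bsk and rpr lower and Jra, Mmp1, upd1 and scaf higher of 14 genes, did not pass (camera adjusted p = 0.373). Adjusted over the list alone 6 were higher and 2 lower. Of the risers, Mmp1 lost its call without CR32027-IR1 replicate 2 or 3 (0.05 and 0.0625) or OreR replicate 1, 2 or 3 (0.0753, 0.0913 and 0.0523). Jra lost its call without any library except CR32027-IR1 replicate 2 and OreR replicate 3 (0.0501 to 0.123), upd1 without any except CR32027-IR2 replicate 1 (0.0557 to 0.132), and scaf, named after its values were seen, without any except CR32027-IR2 replicate 3 and OreR replicate 1 (0.0579 to 0.136).

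Single genes outside these lists differed as well. The embryonic segmentation gene ftz was listed at 0 in all OreR libraries and at 8.51 ± 0.632 RPKM in the libraries labelled CR32027-IR1. The noncoding RNA CR31044 rose from 2.36 ± 0.306 to 23.6 RPKM (limma, adjusted p = 8.8e-08), along with mir-996, which lies within it and can share its reads. Obp56a, an odorant-binding protein gene, rose from 2.27 ± 0.547 to 13.1 ± 1.05 RPKM (adjusted p = 3.58e-05). The antisense RNA CR43767 fell from 14.8 ± 1.07 RPKM by 3.77 on the log2 scale (adjusted p = 5.73e-09). The adjacent genes Hsc70-2 and CG31157 had 1470 and 609 reads over the OreR libraries, against 1 and 3 in those labelled CR32027-IR1.

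In all, 1019 of 7437 genes passed, 453 higher and 566 lower, 37 of them by at least 2-fold. The count was 612 with only these genotypes fitted, 546 without CR32027-IR1 replicate 1, 653 without OreR replicate 1 and 485 without OreR replicate 2. Without CR32027-IR1 replicate 2 the balance turned, with 721 higher and 599 lower. The calls of Mmp1, rpr and Jra were also lost with only these genotypes fitted (0.0677, 0.0694 and 0.0821) and with no filter on low values (0.0573, 0.0741 and 0.0557).

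In CR32027-IR2, the genotype with less CR32027, 9 of 14 genes of the JNK stress kinase pathway and wound response rose. Camera gave this list adjusted p = 1.36e-11, and adjusted p = 0.111 with an estimated correlation. Fathers of CR32027-IR2 and OreR came from different stocks, so lower CR32027 cannot be told apart from other differences of the stocks. Mmp1, a matrix metalloproteinase that degrades basement membrane, rose from 4.57 ± 0.171 to 15.4 ± 1 RPKM (log2 change 1.56; limma, adjusted p = 9.78e-06). The JNK phosphatase gene puc rose from 2.06 ± 0.368 to 4.06 ± 0.14 RPKM (0.73; adjusted p = 0.0021), and rpr from 24 ± 4.02 to 49.9 ± 3.78 (adjusted p = 0.00245). ImpL2, a secreted antagonist of insulin signalling, rose from 1.72 ± 0.26 to 6.61 ± 0.56 RPKM (adjusted p = 6.05e-05), and Ldh from 2.3 ± 0.32 to 8.87 ± 1.3 (adjusted p = 0.000399).

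Of the 14 JNK and wound genes 0 fell, and 11 rose when adjusted over the list alone. Besides Mmp1, puc and rpr, the Jun gene Jra rose by 0.53 on the log2 scale (limma, adjusted p = 0.00126). Named after their values were seen, the TNF receptor gene grnd (0.4; 0.00476) and the Fos gene kay (0.38; 0.00772) rose as well. The remaining calls were upd1 and, named after their values were seen, Gadd45 and scaf. Gadd45 lost its call without CR32027-IR2 replicate 1 or 3 (0.133 and 0.146) or OreR replicate 1 or 2 (0.138 and 0.158). Without any library except CR32027-IR1 replicates 2 and 3 and CR32027-IR2 replicate 1 the upd1 call was lost (0.0587 to 0.14), and without any except CR32027-IR1 replicates 2 and 3 and OreR replicate 1 that of scaf (0.0653 to 0.135).

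**Figure D2:**
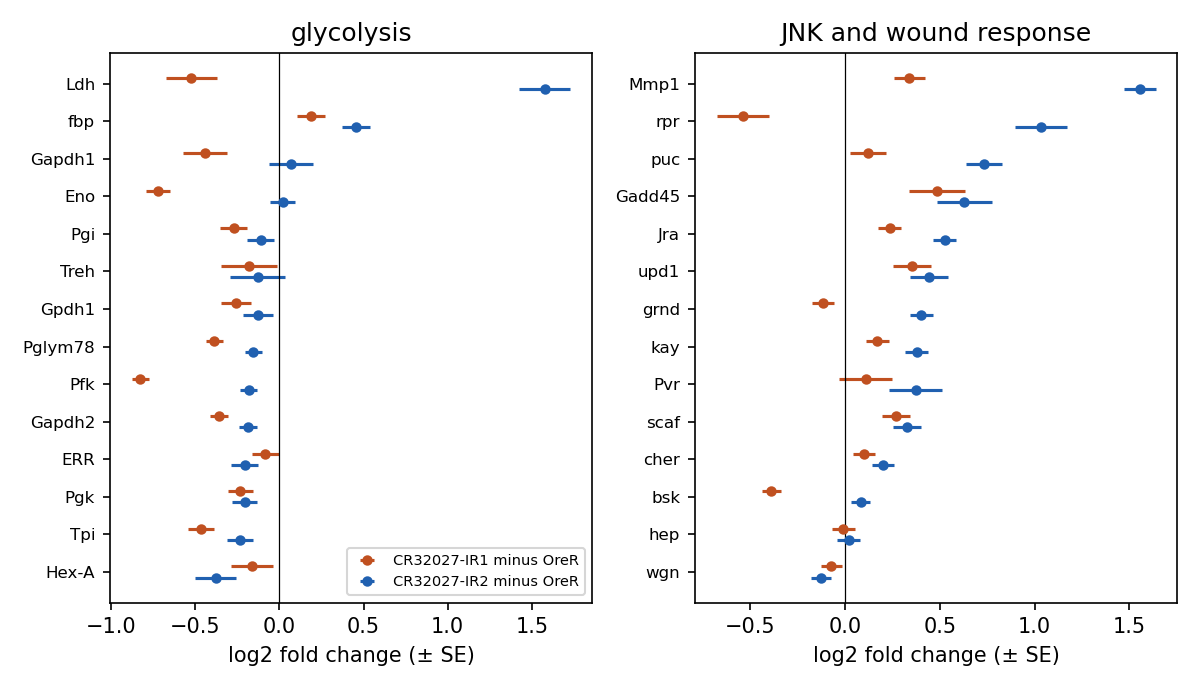
Log2 fold change against OreR (points, ± SE from limma) of the measured glycolysis genes (left) and JNK and wound response genes (right), for CR32027-IR1 and CR32027-IR2. Pfk stands at -0.83 in the libraries labelled CR32027-IR1 and Mmp1 at 1.56 in CR32027-IR2.

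In the apoptosis list rpr and the stress-response transcription factor gene Xrp1 rose, 2 of 13 genes (camera adjusted p = 0.0298; adjusted p = 0.298 with an estimated correlation). Xrp1 lost its call without CR32027-IR2 replicate 1 or 2 (0.0541 and 0.0581). The list did not pass without CR32027-IR1 replicate 3 (0.0533), CR32027-IR2 replicate 1 or 3 (0.082 and 0.0501) or OreR replicate 2 (0.0612).

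Hormone-linked and cuticle genes included large rises. In the ecdysone list ImpL2, Ldh, the ecdysone-inactivating enzyme gene Cyp18a1 and the cuticle gene Edg78E rose and Cth fell, of 23 genes, and the list did not pass (camera adjusted p = 0.0809). Cth, named after its values were seen, lost its call without CR32027-IR2 replicate 1, 2 or 3 (0.0649, 0.0902 and 0.0633) or OreR replicate 1 or 2 (0.0649 and 0.081). Among 28 cuticle genes 5 rose and 2 fell (camera adjusted p = 0.258), led by TwdlE, from 5.16 ± 1.05 to 29.4 ± 2.53 RPKM (limma, adjusted p = 9.78e-06). There were 5 rises and 3 falls when adjusted over the list alone. The others were Edg78E and Cpr64Ac, higher, and, named after their values were seen, mey and nyo, higher, and Cpr57A and Cpr66D, lower. Of these, mey lost its call without CR32027-IR2 replicate 3 (0.0539) or OreR replicate 1 or 2 (0.0504 and 0.0611), Cpr57A without CR32027-IR2 replicate 1 or 2 (0.0591 and 0.0632) or OreR replicate 1 or 2 (0.0624 and 0.0758), and Cpr66D without CR32027-IR2 replicate 2 or 3 (0.0579 and 0.0539). The nyo call was lost without CR32027-IR1 replicate 1 (0.0706), CR32027-IR2 replicate 2 or 3 (0.152 and 0.161) or OreR replicate 1, 2 or 3 (0.13, 0.134 and 0.102). Dopa decarboxylase (Ddc), which acts in cuticle hardening, rose from 0.417 ± 0.207 to 5.16 ± 0.517 RPKM (adjusted p = 0.000154). The glutathione transferase gene GstD1 rose from 622 ± 33.2 to 827 ± 22.8 RPKM (adjusted p = 0.00263). The glycolysis list did not pass (camera adjusted p = 0.335): Ldh and the gluconeogenic gene fbp were called higher, and 7 of 14 genes were called lower when adjusted over the list alone. fbp, named after its values were seen, lost its call without CR32027-IR2 replicate 1 or 2 (0.0583 and 0.0654).

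Heat shock genes passed with 2 of 20 called higher, Hsp70Ba and Hsp70Bb (camera adjusted p = 5.1e-07, and 0.766 with an estimated correlation). Adjusted over the list alone 4 were higher. Because the Hsp70Bb promoter is part of UAS vectors, signal from a transgene could not be told apart from a heat shock response. The neuron and glia list had moody and nrv2 higher of 3 genes (camera adjusted p = 0.0111; adjusted p = 0.298 with an estimated correlation). The glial receptor gene moody was 6.15 ± 0.589 RPKM (limma, adjusted p = 3.52e-05), and the neuronal gene elav was 3.54 ± 0.151 in OreR and 3.4 ± 0.118 here (adjusted p = 0.784). nrv2, also in the septate junction list and called in the libraries labelled CR32027-IR1 as well (adjusted p = 0.00247), lost its call here without CR32027-IR1 replicate 1 (0.0604), CR32027-IR2 replicate 1, 2 or 3 (0.0817, 0.126 and 0.0545) or OreR replicate 1 or 2 (0.116 and 0.102). The immune list had Dif and vir-1 higher of 5 genes (camera adjusted p = 0.0111; adjusted p = 0.298 with an estimated correlation), and 3 higher when adjusted over the list alone. Dif lost its call without CR32027-IR2 replicate 2 (0.057), and vir-1 without any library except CR32027-IR1 replicates 2 and 3 (0.0536 to 0.12).

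Ribosomal proteins, mitosis and JAK-STAT passed with 1 called gene each. They were RpS19b, lower, of 82 (median log2 change -0.08; camera adjusted p = 0.0111; adjusted p = 0.926 with an estimated correlation), borr, higher, of 31 (0.0192; adjusted p = 0.926 with an estimated correlation) and upd1, higher, of 6 (0.0356; adjusted p = 0.766 with an estimated correlation). The ribosomal list did not pass without CR32027-IR2 replicate 1 (0.141) or OreR replicate 1 (0.336), and the mitosis list without CR32027-IR2 replicate 2 (0.261) or OreR replicate 1 (0.336). The JAK-STAT list did not pass without CR32027-IR1 replicate 3 (0.0505), CR32027-IR2 replicate 1 or 3 (0.0516 and 0.111) or OreR replicate 1 or 2 (0.191 and 0.0698), with genes of at least 5 RPKM (0.182), with median-of-ratios scaling (0.0523) or with limma voom on recovered reads of genes averaging at least 50 reads (0.114). RpS19b lost its call without CR32027-IR2 replicate 2 or 3 (0.0604 and 0.0649), and borr without CR32027-IR2 replicate 1, 2 or 3 (0.0541, 0.121 and 0.0937) or OreR replicate 1 or 3 (0.106 and 0.0845). Of Hedgehog genes disp, which acts in ligand release, fell from 18.6 ± 0.911 to 11.1 ± 0.313 RPKM (limma, adjusted p = 0.000154), and the list, with disp and en lower of 15 genes and 3 lower when adjusted over the list alone, did not pass (camera adjusted p = 0.335). The call of en, named after its values were seen, was lost without CR32027-IR1 replicate 1 (0.0558), CR32027-IR2 replicate 2 or 3 (0.123 each) or OreR replicate 1, 2 or 3 (0.0662, 0.1 and 0.0976).

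Some genes at or near 0 in OreR had reads in CR32027-IR2. CG43182 was listed at 0 in all OreR libraries and at 33.1 ± 4.7 RPKM here. It lies on the X, which males of all genotypes took from the driver mothers, and whether its signal comes from that X was not tested. The gustatory receptor gene Gr64a was listed at 0 in OreR and at 5.05 ± 0.784 in CR32027-IR2. CG11594, next to Gr64a, had 2 reads over the OreR libraries and 1181 here. CG6912 fell from 3.97 ± 0.806 to 0.0979 ± 0.0317 RPKM (limma, adjusted p = 8.73e-06).

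In all, 383 of 7437 genes passed, 218 higher and 165 lower, 53 of them by at least 2-fold. The count was 527 with only these genotypes fitted, 232, 187 and 214 without CR32027-IR2 replicate 1, 2 or 3, and 217 without OreR replicate 1. Without OreR replicate 2 it was 139 higher and 66 lower.

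Genes that differed from OreR in the same direction in both hairpin genotypes were examined next. The heat-inducible chaperone gene Hsp70Bb, whose promoter is part of UAS vectors, rose from 25.5 ± 1.71 RPKM in OreR to 352 ± 68.9 in the libraries labelled CR32027-IR1 and 144 ± 17.3 in CR32027-IR2. Its near-identical copy Hsp70Ba rose from 4.94 ± 1.17 to 110 ± 51.7 and 42.1 ± 10.2, and since such copies share reads their separate values are uncertain. CR32027-IR1 replicate 2 stood apart, with Hsp70Ba at 169.3 RPKM against 78.4 and 81.2 in replicates 1 and 3. The copies Hsp70Bbb and Hsp70Bc were at 129.5 and 153.9 in replicate 2, against 8.96 and 10.8 in replicate 1 and 12.3 and 13.6 in replicate 3. The cuticle gene TwdlE rose to 9.21 ± 1.04 in the libraries labelled CR32027-IR1 (limma, adjusted p = 0.00501) and 29.4 ± 2.53 in CR32027-IR2. CG5618 fell from 14 ± 1.71 RPKM to 4.9 ± 0.473 and 3.63 ± 0.23 (adjusted p = 4.85e-05 and 1.18e-05), and CG17186 from 21.1 ± 2.75 to 8.57 ± 1.14 and 6.58 ± 0.419 (0.000307 and 6.05e-05).

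**Figure D3:**
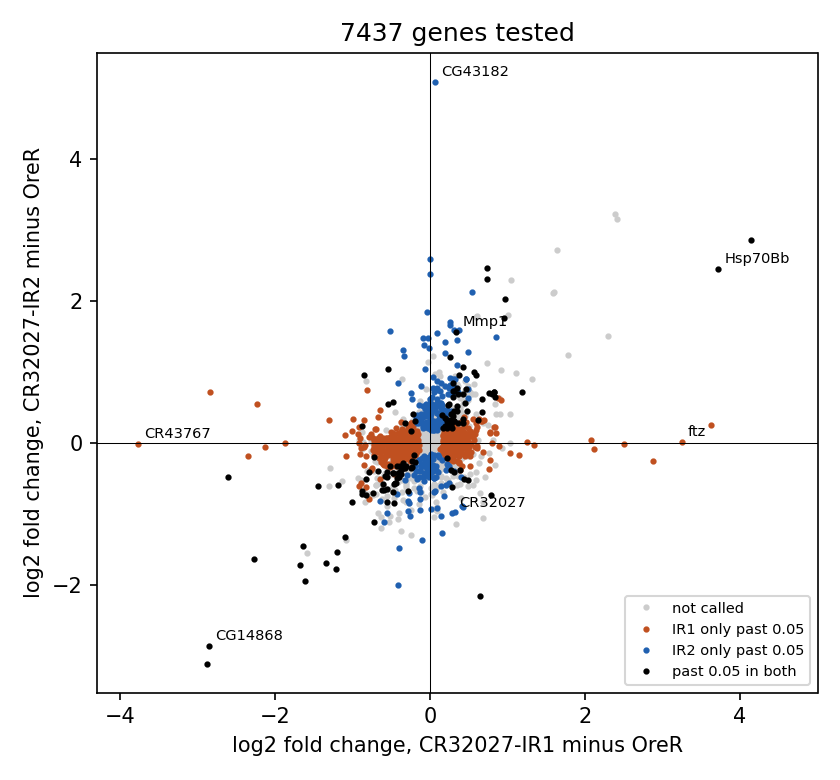
Log2 fold change against OreR of 7437 genes in the libraries labelled CR32027-IR1 (horizontal axis) and CR32027-IR2 (vertical axis), coloured by which comparison passed adjusted p 0.05. In both comparisons with the same sign 116 genes passed.

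CG14868 had log2 changes of -2.85 and -2.87 (limma, adjusted p = 4.5e-07 and 9.54e-07). Unc-115b rose from 36.4 ± 2.32 RPKM to 65.1 ± 3.7 and 60.1 ± 1.56. The span of p24-2 overlaps it, so their reads cannot be separated, and p24-2 rose from 34.1 ± 1.98 to 61.2 ± 3.4 and 56.4 ± 1.63. Nearby Unc-115a, CG18542, CG32939 and eca, named after their values were seen, also had higher means in both. Unc-115a went from 14.2 ± 0.307 RPKM to 25.4 ± 1.4 and 23.4 ± 0.55. CG9444 there went the other way, from 0.585 ± 0.182 to 0.549 ± 0.239 and 0.365 ± 0.0694. Why the block differed was not tested. Mmp1 passed in both, at 6.06 ± 0.735 RPKM in the libraries labelled CR32027-IR1 (adjusted p = 0.0269), a call lost without CR32027-IR1 replicate 2 or 3 (0.05 and 0.0625) or OreR replicate 1, 2 or 3 (0.0753, 0.0913 and 0.0523).

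In both with the same sign 116 genes passed, 57 higher and 59 lower, and 18 passed with opposite signs. Independent lists would share 13.3 higher and 12.6 lower genes. Unchanged groups simulated against the same controls shared 0.02 on average, near 0 by construction, since few genes are called where none is changed. That value does not give the overlap that shared controls would add to lists of 1019 and 383 called genes. The correlation of fold changes across genes was 0.369 against 0.5 in those simulations, and the covariance 0.0263 against 0.0065, a difference of 0.0198. With 3 OreR libraries the controls were not split, and part of the excess may come from the shared controls. The count was 69 without CR32027-IR1 replicate 1, 61, 51 and 64 without CR32027-IR2 replicate 1, 2 or 3, and 57 and 43 without OreR replicate 1 or 2.

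The hairpin genotypes were also compared directly. Pfk, Ldh, ac, sc, Mmp1, puc, rpr, ImpL2 and TwdlE were lower in the libraries labelled CR32027-IR1 than in CR32027-IR2. As CR32027-IR1 minus CR32027-IR2, the log2 difference was -2.1 for Ldh (limma, adjusted p = 4.66e-05), -1.58 for rpr (0.000143), -1.57 for ImpL2 (3.16e-05), -0.64 for Pfk (6.65e-05) and -0.62 for ac (0.000535). Of 82 ribosomal protein genes 28 were higher and 0 lower (camera adjusted p = 6.11e-09; adjusted p = 0.918 with an estimated correlation). That number was 11, 60 and 18 without CR32027-IR1 replicate 1, 2 or 3, 8, 5 and 12 without CR32027-IR2 replicate 1, 2 or 3, and 15 without OreR replicate 2. With quantile normalization 21 were higher and 2 lower, and adjusted over the list alone 34 were higher. In the JNK list 7 of 14 genes were lower (3.67e-05) and in the glycolysis list 7 of 14 (0.000437), each with adjusted p = 0.416 with an estimated correlation. The glycolysis count was 4 without CR32027-IR1 replicate 1 or CR32027-IR2 replicate 1 or 2, and 8 adjusted over the list alone. The sensory organ list, with 3 of 10 genes lower, did not pass (camera adjusted p = 0.168).

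In the same contrast 6 of 23 ecdysone genes were lower (7 adjusted over the list alone; camera adjusted p = 0.0081; adjusted p = 0.856 with an estimated correlation), 3 of 7 tracheal genes, Gasp, obst-A and serp (0.028; adjusted p = 0.712 with an estimated correlation) and 9 of 28 cuticle genes, with Cpr49Ag, Cpr67Fa2 and Cpr57A higher (0.0415; adjusted p = 0.545 with an estimated correlation). Without CR32027-IR1 replicate 3 none of these 3 lists passed (0.22, 0.129 and 0.111), and the cuticle list did not pass without CR32027-IR1 replicate 1 (0.0652) or CR32027-IR2 replicate 3 (0.246), which left 5 cuticle genes lower. Gasp lost its call without CR32027-IR2 replicate 2 (0.0504), and obst-A without any library except CR32027-IR1 replicate 1 and OreR replicates 2 and 3 (0.0501 to 0.0981). In all, 1625 of 7437 genes passed, 913 higher and 712 lower in the libraries labelled CR32027-IR1. With median-of-ratios scaling the balance turned, with 768 higher and 891 lower. The count was 981 without CR32027-IR1 replicate 1 (467 higher, 514 lower) and 1079, 970 and 1002 without CR32027-IR2 replicate 1, 2 or 3, the last with 477 higher and 525 lower.

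Male offspring took their X from the driver mothers and a set of autosomes from OreR or hairpin fathers, so X-linked and autosomal genes were compared. X-linked genes were called less often. Of 1208 X-linked and 5854 autosomal genes 131 and 835 passed in the libraries labelled CR32027-IR1 (odds ratio 0.731; Fisher's exact test, two-sided, p = 0.00149, adjusted p = 0.00348). In CR32027-IR2 the numbers were 39 and 331 (odds ratio 0.557; Fisher's exact test, p = 0.000371, adjusted p = 0.0013), and for genes changed alike in both 9 and 103 (0.419, p = 0.00763, adjusted p = 0.0107). Between the hairpins they were 214 and 1334 (0.73; Fisher's exact test, p = 8.26e-05, adjusted p = 0.000578). Among genes called with at least 2-fold change, 0 X-linked and 36 autosomal passed in the libraries labelled CR32027-IR1 (Fisher's exact test, p = 0.00269, adjusted p = 0.0047). The numbers were 5 and 45 in CR32027-IR2 (odds ratio 0.537; Fisher's exact test, p = 0.256) and 0 and 11 in both (Fisher's exact test, p = 0.23), with adjusted p = 0.256 each. Adjustment was over these 7 tests. With genes called at adjusted p under 0.01, the odds ratios against OreR were 0.799 and 0.773, and 0.179 for both, and none passed (Fisher's exact test, p = 0.17, 0.327 and 0.0735). With genes of at least 5 RPKM the odds ratio for both was 0.458 and did not pass (Fisher's exact test, p = 0.0511).

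Markers of other cells were examined as well. Of 8 notum genes, the tissue cut away, Ance and Doc1 were lower in the libraries labelled CR32027-IR1 (camera adjusted p = 0.438) and 0 were called in CR32027-IR2 (0.552), where Ance, Doc1 and Doc2 were lower when adjusted over the list alone. Doc1 lost its call without OreR replicate 2 or 3 (0.0811 and 0.0906). Of 5 hemocyte genes (camera adjusted p = 0.259) crq, a phagocytosis receptor gene, fell from 10.5 ± 0.223 to 7.68 ± 0.125 RPKM in the libraries labelled CR32027-IR1 (limma, adjusted p = 0.0011). The hemocyte genes Col4a1, NimC1 and Sr-CI had their lowest values of the 9 libraries in CR32027-IR1 replicate 2, at 0.447, 0.278 and 0.292 RPKM. They were at 2.26, 1.86 and 1.6 in replicate 1 and at 2.6, 1.97 and 1.93 in replicate 3 of that genotype, and were not called (limma, adjusted p = 0.771, 0.918 and 0.852). PPO2, a phenoloxidase gene outside that list, was 12 ± 5.9 RPKM in OreR, 3.4 ± 2.44 in the libraries labelled CR32027-IR1 (log2 change -1.61; limma, adjusted p = 0.0447) and 2.14 ± 0.617 in CR32027-IR2 (-1.95; 0.0402). The first PPO2 call was lost without any library except CR32027-IR1 replicate 3 and OreR replicate 1 (0.0592 to 0.143), and the second without any except CR32027-IR1 replicates 2 and 3 and OreR replicate 1 (0.0701 to 0.147). Both were lost with a pseudocount of 0.1 (0.0523 and 0.0504) or no filter on low values (0.104 and 0.0956). The first was also lost without an intensity trend (0.0503), with array weights (0.112) or with only these genotypes fitted (0.0895), and the second with limma voom on recovered reads (0.0523). The neuron and glia list had 1 of 3 genes higher in the libraries labelled CR32027-IR1, nrv2 (camera adjusted p = 0.259), and 2 of 3 in CR32027-IR2 (camera adjusted p = 0.0111; adjusted p = 0.298 with an estimated correlation).

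Of 7 tracheal genes Gasp, obst-A and trh were lower in those labelled CR32027-IR1 (camera adjusted p = 0.127; 4 lower and 1 higher adjusted over the list alone), with trh lost without OreR replicate 2 (0.0539). In CR32027-IR2 the tracheal gene serp rose from 16.6 ± 2.37 to 36.4 ± 2.52 RPKM (limma, adjusted p = 0.000974) and trh fell by 0.33 on the log2 scale (adjusted p = 0.0427), and the list did not pass (camera adjusted p = 0.967; 2 higher and 2 lower adjusted over the list alone). The trh call there was lost without CR32027-IR2 replicate 1, 2 or 3 (0.096, 0.156 and 0.13) or OreR replicate 1 or 2 (0.133 and 0.163). Adult muscle precursor, larval muscle and peripodial lists, with 4, 3 and 3 genes, had 0 calls over all genes in either comparison with OreR. Adjusted over the list alone, the larval muscle gene Act87E was lower in the libraries labelled CR32027-IR1 (camera adjusted p = 0.657), and Act57B and Act87E were higher in CR32027-IR2 (0.0746). Leg disc, fat body and salivary glue lists had 2, 1 and 1 genes measured and were not tested.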

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

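The tests of Indy reads, of exchanged labels and of neighbouring genes, and the bounds set for the X-linkage test, were chosen after the results were seen.

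CR32027 differed between the hairpin genotypes, by 1.28 on the log2 scale as CR32027-IR1 minus CR32027-IR2, and was not lower than OreR in the libraries labelled CR32027-IR1. Reads of Indy as the source of the difference between the hairpin genotypes are argued against, because the log2 ratio of CR32027 to Indy was higher there than in CR32027-IR2 by 1.59 (95% interval 0.49 to 2.7; exact permutation p = 0.1, the smallest possible). Against OreR that ratio differed by 0 (95% interval -1.1 to 1.11; exact permutation p = 1), an interval too wide to decide, so Indy reads stay open for that comparison. An exchange of the CR32027-IR1 and OreR labels is argued against by Hsp70Bb. It was not settled, because w leaned the other way without passing. Hsp70Bb, whose promoter is part of UAS vectors, was higher in CR32027-IR1 than in OreR by 3.72 (95% interval 3.42 to 4.01), and was also higher in CR32027-IR2. Dcr-2 was lower than in OreR in both hairpin genotypes (log2 changes -0.88 and -0.68). The other way, w differed by -0.16 in CR32027-IR1 (-0.29 to -0.03) and did not pass (limma, adjusted p = 0.103). Counting of the hairpin transcript at CR32027, a hairpin that does not lower the RNA and another stock than the label says stay open and were not tested.

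The hairpin genotypes differed by a direct test in 1625 genes, against at most 0 in the other splits of those 6 libraries. For the libraries labelled CR32027-IR1 against OreR the real grouping gave 1019 genes and the highest other split 4, and for CR32027-IR2 against OreR 383 and 0. In each of the 3 comparisons 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Opposite directions against OreR were seen for 18 genes. Of these 9 were higher in CR32027-IR1 and lower in CR32027-IR2, where independent lists give 10.1. The other 9 went the other way, where independent lists give 16.6. By the direct test rpr differed by -1.58 and Mmp1 by -1.22, as CR32027-IR1 minus CR32027-IR2.

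For the 116 genes changed alike in both hairpin genotypes, 2 of 100 drawn splits of the 9 libraries (of 840), the real one among them, gave as many. The highest other split gave 120 and set the 3 CR32027-IR2 libraries as the reference, which points to a structure of the samples. With CR32027-IR1 as the reference 692 genes differed alike from both other genotypes, and with CR32027-IR2 246, both more than with OreR. The splits show that libraries group by genotype and cannot exclude chance for a change shared by the hairpins. A candidate explanation is that paternal autosomes differ between OreR and the hairpin stocks: X-linked genes, whose X came from shared mothers, were called less often (odds ratio 0.419, 95% interval 0.186 to 0.83), a call lost at adjusted p under 0.01 (0.179; Fisher's exact test, p = 0.0735) and with genes of at least 5 RPKM (0.458; p = 0.0511). An effect of hairpin expression stays open, untested. Loss of CR32027 was measured in 1 of the 2 genotypes.

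Neighbouring genes were called together more often than by chance placement. In the libraries labelled CR32027-IR1 74 of 5731 neighbouring pairs were called in one direction, against 54.8 on average in 10000 permutations within arms (95% range 41 to 69, p = 0.0038), and in CR32027-IR2 17 against 8.2 (3 to 14, p = 0.0034). Shared regulation and differences of the parental chromosomes stay open, and no biological explanation was tested.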

How the results depend on the processing

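Array weights gene by gene, voom on recovered reads and protein-coding genes alone were chosen after the data were seen. The numbers of genes past the threshold (1019 for CR32027-IR1, 383 for CR32027-IR2, 1625 between them and 116 in both) stayed within 1.5 times under other pseudocounts, filters, scalings, no trend, voom and protein-coding genes alone. They were 375, 156, 663 and 29 at adjusted p under 0.01, and 147, 144, 224 and 35 at 1.5-fold or more, stricter by construction. Array weights gave 371, 972 and 706 for the first 3, from an estimate that stopped before converging and gave CR32027-IR1 replicate 1 a weight of 0.01. Estimated gene by gene, that weight was 4.48 and the numbers were 2313, 779, 3294 and 267, so weights are not a stable choice here. The balance of higher to lower calls moved with them: 110 to 261, 449 to 523 and 305 to 401 with array weights, and 1318 to 995, 386 to 393 and 2043 to 1251 gene by gene. Fitting only the compared genotypes gave 612 for CR32027-IR1 and 527 for CR32027-IR2, against 1019 and 383 with all 9 libraries. The gap between these 2 counts thus depends on which libraries are fitted, and the cause was not tested. The replicate block gave 565 for CR32027-IR1, 222 for CR32027-IR2 and 54 in both. Same-numbered libraries shared only a number: correlations of their deviations were -0.237 to 0.116, over 0.1 in 1 of 9 pairs. Leaving out each library gave 485 to 1320, 187 to 504, 970 to 2159 and 43 to 134, with fewer samples.

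The log2 change of CR32027 without each library was 0.152 to 0.392 for CR32027-IR1, -1.105 to -0.787 for CR32027-IR2 and 1.073 to 1.391 between them. The CR32027-IR2 call was lost without OreR replicate 2 (-0.885), and a filter at 5 RPKM removes the gene. Lists past the threshold went from 6 and 8 to 0 and 0 with an estimated correlation and to 3 and 5 with fry. For CR32027-IR2 they were 5 at a mean of 5 RPKM. Without each library they were 5 to 9 and 5 to 11. The fry counts include lists that camera did not call. With fry the Hedgehog, wing pouch, S phase and ribosomal lists were lost for CR32027-IR1 (fry adjusted p = 0.0587, 0.0587, 0.2 and 0.239). For CR32027-IR2 the heat shock, JAK-STAT, mitosis and ribosomal lists were lost (fry adjusted p = 0.14, 0.188, 0.665 and 0.665). The X-linkage odds ratios lost their call at adjusted p under 0.01 (0.799, 0.773 and 0.179), where fewer genes are called, and for both hairpins at 5 RPKM (0.458; the cause was not tested). Of single named genes over all settings 3272 values kept their side of the threshold, 425 lost it, 2 passed it and 0 reversed; of lists 178 kept it and 44 lost it. Few reads limit CR32027 itself, at 18 to 164 per library.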

Other observations

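The tests and the genes named here were chosen after the data were seen. Genes under the RPKM filter with at least 50 reads on average were tested with limma voom on recovered reads (330 genes): 19 were higher and 36 lower in the libraries labelled CR32027-IR1, and 26 higher and 12 lower in CR32027-IR2. In CR32027-IR2 they added 2 members of the JNK and wound list. The transcription factor gene Ets21C rose from 32.3 ± 10.1 to 311.7 ± 60.6 reads per library (mean ± SD, n = 3; limma voom, adjusted p = 0.00326) and the growth factor gene Pvf1 from 105.7 ± 29 to 343.7 ± 79.6 (adjusted p = 0.000509). In the libraries labelled CR32027-IR1 Ets21C was 113 ± 99.2 (adjusted p = 0.12) and Pvf1 128.7 ± 37.2 (adjusted p = 0.69). Traf4, an adaptor of TNF receptor signalling, rose in CR32027-IR2 from 264 ± 61.4 to 489.3 ± 127 reads (adjusted p = 0.0033) and fell to 169.7 ± 9.1 in the libraries labelled CR32027-IR1 (adjusted p = 0.0151).

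The cadherin gene CadN2 fell in the libraries labelled CR32027-IR1 from 2453.3 ± 362.1 to 1282 ± 35 reads (limma voom, adjusted p = 2.27e-06), as did Dscam1, from 1448 ± 301.9 to 787.3 ± 57.6 (6.04e-05), and nrm, from 760.7 ± 149.7 to 178.7 ± 21.1 (1.94e-05). In CR32027-IR2 these were 2421.7 ± 388.4, 1336.7 ± 215.6 and 1019.7 ± 275 (adjusted p = 0.425, 0.245 and 0.0774). The kinesin gene Klp54D had 373 ± 7.2 reads per library in OreR and 0.3 ± 0.6 in each hairpin genotype, and Root 387.3 ± 108.3 in OreR, 4.3 ± 1.5 in the libraries labelled CR32027-IR1 and 5.3 ± 0.6 in CR32027-IR2.

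On 3L (BDGP6) CG11594 and the sugar receptor genes Gr64a to Gr64f, from 4022700 to 4037575, were near 0 in OreR and in the libraries labelled CR32027-IR1, and between 1.08 ± 0.236 (Gr64f) and 5.05 ± 0.784 RPKM (Gr64a) in CR32027-IR2. Gene models in this cluster overlap, so single values are uncertain. At its borders Mul1 was 4.16 ± 0.536 RPKM in OreR and 3.79 ± 0.21 in CR32027-IR2, and CG11593 29.5 ± 0.443 and 34 ± 0.332. On the X, CG43182 (353067 to 353317) lies upstream of the pigment gene y (start 356509), which was listed at 0 in OreR and at 0.365 ± 0.0104 RPKM in CR32027-IR2.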
